A study of Mus musculus with 3 samples.

How the data were processed

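Granulosa cells came from ovaries of C57BL/6 females aged postnatal day 21 to 28 that had received 4 IU of eCG, taken before (0 h) and 4 h and 12 h after 5 IU of hCG, per the labels' protocols. RNA of 3 mice per time point was extracted with a column kit and libraries were made with an Illumina mRNA kit, per the labels' protocols. The labels give 1 library per time, and whether RNA was pooled before library preparation is not given in the sources used here, nor is strandedness or read length. Genes that overlap on opposite strands, and near-identical copies such as globin, Hsd3b1-family and ribosomal protein genes, are therefore uncertain.

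The values analysed are the deposited FPKM of RefSeq isoforms, fragments per kilobase of transcript scaled for the number of mapped fragments, with a lower and an upper bound for each. CASAVA 1.8, TopHat2 2.1.1, Cufflinks 2.2.1 and the mm10 genome are named in the submitters' processing notes, without their role or order. The level of the deposited FPKM intervals is not stated, and 12 estimates marked as failed had no bounds. For each of 34535 isoforms there was 1 value in each of the 3 libraries. Matching RefSeq accessions to gene symbols of GRCm38.p6, the assembly that mm10 names, placed 34169 isoforms; 193 more were placed through the GENCODE annotation and 173 had no match and were left out. Isoform FPKM were summed to 24225 genes, 5452 of which had several isoforms, and bounds were combined as the root of the summed squared half-widths, which assumes independent isoform estimates. Coordinates are 1-based positions in GRCm38.

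Depth was read from the steps between low FPKM values of genes with 1 isoform longer than 1000 nt. After an allowance for fragment length, 70.6%, 69.1% and 71.3% of values below 10 fragments lay within 0.1 of a whole number of fragments at 0, 4 and 12 h, where chance gives 20%. The steps correspond to 13400000, 11900000 and 11700000 fragments, so that 1 fragment on a transcript of 2 kb is worth 0.0374, 0.0419 and 0.0429 FPKM. Values of 0 cannot be told from a failed estimate in this file, since some ubiquitous genes are also at or near 0, and such genes are given as listed at 0 without a fold. Summed FPKM were 502800, 622447 and 474116, of which protein-coding genes held 79.8%, 75.3% and 81.3% and microRNA and snoRNA genes most of the rest.

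A log2 fold was log2 of the later FPKM + 1 over the earlier FPKM + 1. A gene was called higher or lower at a fold of at least 2 with at least 1 FPKM in 1 of the 2 libraries. With 1 library per time this is a rule of size and not a test, and no p-value was computed. Time courses were made from the calls of the 3 comparisons. Isoform switches were changes of at least 50 percentage points in 1 isoform's share of its gene, in genes with at least 10 FPKM in both libraries. For each of 30 gene lists (biological groups, markers of 8 other cell types and technical controls) the median log2 fold of members with at least 1 FPKM was set among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries. Ly6g, Hbb-bt and Muc16 had no matched transcript.

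The rules, the 30 lists and the alternatives below were fixed before the data were examined; the length trend correction, the isoform interval requirement, the rescaling to the mean of the library sums and 9 further gene families were added after. Genes named in the text are, per comparison, the 10 with the largest fold in each direction among those with at least 5 FPKM in 1 of the 2 libraries, leaving out symbols with the prefixes or suffixes of microRNA, snoRNA, other small RNA, predicted, unnamed and pseudogene entries (the snoRNA AF357399 has none of these and is named); up to 4 members of each list with the largest fold and at least 1 of each direction; the 3 genes with the largest isoform change; and 20 genes fixed in advance. Genes named for the families in the closing part were picked as examples after their values were seen. The text names the ones that describe each group, not every gene the rule gives. Alternatives were pseudocounts of 0.1 and 5 FPKM, no filter or a filter of 5 FPKM, median-of-ratios scaling over genes with at least 5 FPKM in all libraries, rescaling to a common sum of 1000000 FPKM, the main isoform in place of the sum, leaving out short RNAs, thresholds of 1.5-fold and 4-fold, deposited intervals that lie apart, and other isoform floors and share changes.

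The steps were tested on simulated libraries drawn as Poisson fragments from the 0 h values of all 24225 genes. Changed genes were picked among those with at least 5 FPKM at 0 h, so the recovery of changes in lower genes was not tested. For the 0 to 4 h comparison, each of 50 genes changed 3-fold, 50 changed 4-fold and 50 changed 8-fold was called, 0 of 50 changed 1.5-fold was called, and 0.153% of 12425 unchanged genes were called. For the 0 to 12 h comparison 49 of 50 genes changed 3-fold were called. Of 60 genes with swapped isoforms 60 were recovered among 2255, with 0 false switches. The swapped genes were picked for a gap between isoform shares beyond the threshold. Fragments were drawn for each isoform on its own, so errors in dividing shared fragments between isoforms were not simulated. These simulations hold counting noise only, not the spread between mice. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.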

Results

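Messenger RNA was sequenced from granulosa cells, the somatic cells that surround the oocyte in the ovarian follicle, of immature wild-type C57BL/6 mice. Follicle growth had been stimulated with 4 IU of equine chorionic gonadotropin (eCG), and ovulation was then triggered with 5 IU of human chorionic gonadotropin (hCG), which acts on the luteinizing hormone receptor. Cells were collected by puncturing the follicles just before hCG (0 h) and at 4 h and 12 h after it. RNA was taken from 3 mice per time and each time is represented by 1 library, so the 3 libraries have no replicates, no test was run, and each difference given here is a difference between 2 libraries. The spacing of low values placed the depth at 13400000 fragments at 0 h, 11900000 at 4 h and 11700000 at 12 h. At least 1 FPKM (fragments per kilobase of transcript, scaled for depth) was recorded for 12449, 12635 and 12617 of 24225 genes. The intervals given beside levels are the deposited ones and describe the estimate within 1 library, not the spread between mice. Genes are called higher or lower where the fold reached 2 on the log2(FPKM + 1) scale, which understates the change of low genes.

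The comparison of 4 h with 0 h asked which transcripts of granulosa cells differed early after the ovulatory signal. At 4 h the EGF-like growth factors amphiregulin (Areg), epiregulin (Ereg) and betacellulin (Btc), the prostaglandin synthase Ptgs2, the progesterone receptor Pgr and the matrix genes Tnfaip6 and Ptx3 went from under 2 FPKM to more than 100. Areg was at 0.45 FPKM at 0 h and 567 at 4 h (deposited interval 547 to 587), Btc at 1.04 and 762 (747 to 776), Ereg at 0.572 and 363 (355 to 371), and Ptgs2 at 1.76 and 581 (571 to 591). Tnfaip6 was at 1.40 and 1251 FPKM (log2 fold 9.03), Ptx3 at 1.18 and 396 (7.51) and Pgr at 0.191 and 138 (6.86). The estrogen sulfotransferase Sult1e1 was listed at 0 before hCG and at 2316 FPKM at 4 h, and the neuropeptide genes Nts, Nmu and Npy, also listed at 0 before hCG, were at 2009, 266 and 191 FPKM. In the other direction the inhibin beta B subunit Inhbb was at 1354 FPKM at 0 h and 27.0 at 4 h (log2 fold -5.59), followed by Mro (267 and 12.9), Smim10l2a (23.3 and 0.554), Fam162b (18.2 and 0.469) and Kcne2 (19.5 and 0.731).

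By the 2-fold rule 1356 of 13240 genes were higher at 4 h and 931 were lower; 209 were higher and 48 lower by at least 8-fold. Of the genes past the threshold 59.3% were higher on the deposited FPKM scale. With each library rescaled to a common sum, 1213 genes were higher and 2185 lower, a share of 35.7% higher, and the median of all genes moved by -0.29. That sum of 1000000 also raises each value against the pseudocount; with libraries brought to the mean of their own sums, which keeps the level, 1001 genes were higher and 1724 lower (36.7% higher). With median-of-ratios scaling 1333 genes were higher and 950 lower (58.4% higher). Its factors were 0.997, 0.990 and 1.01 for the 0, 4 and 12 h libraries. Counts under it were therefore bound to lie near those on the deposited scale. Part of the larger 4 h sum lay in short RNAs. MicroRNA genes held 54576 FPKM at 0 h and 75472 at 4 h, snoRNA genes 37511 and 62341, and protein-coding genes 401459 and 468577. Changes below are relative to the deposited scale, on which the median log2 fold of all genes was -0.01. In the GRCm38 assembly Areg, Ereg and Btc lie on chromosome 5 at 91139599 to 91148432, 91074617 to 91093649 and 91357261 to 91402994. Sult1e1 lies on the same chromosome at 87575968 to 87591611, Ptgs2 on chromosome 1 at 150100031 to 150108234 and Inhbb on chromosome 1 at 119415463 to 119422248.

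Among the 20 ovulatory mediators, 16 were higher at 4 h, none was lower and 4 were neither, with a median log2 fold of 3.10. The median lay above those of all 10000 random lists of the same size matched on expression. The corepressor Nrip1 was at 11.6 FPKM at 0 h and 7.36 at 4 h. Of the 7 measured genes of the cumulus matrix, which holds the expanding cell mass around the oocyte together, 5 were higher and the median was 3.92, again above all random lists. The proteoglycan Vcan was at 111 FPKM at 0 h and 1806 at 4 h, and the hyaluronan synthase Has2 at 0.111 and 15.9 (13.9 to 17.8). The plot of gene levels over time shows these genes beside genes of steroid synthesis and of the follicular phase.

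**Figure D1:**
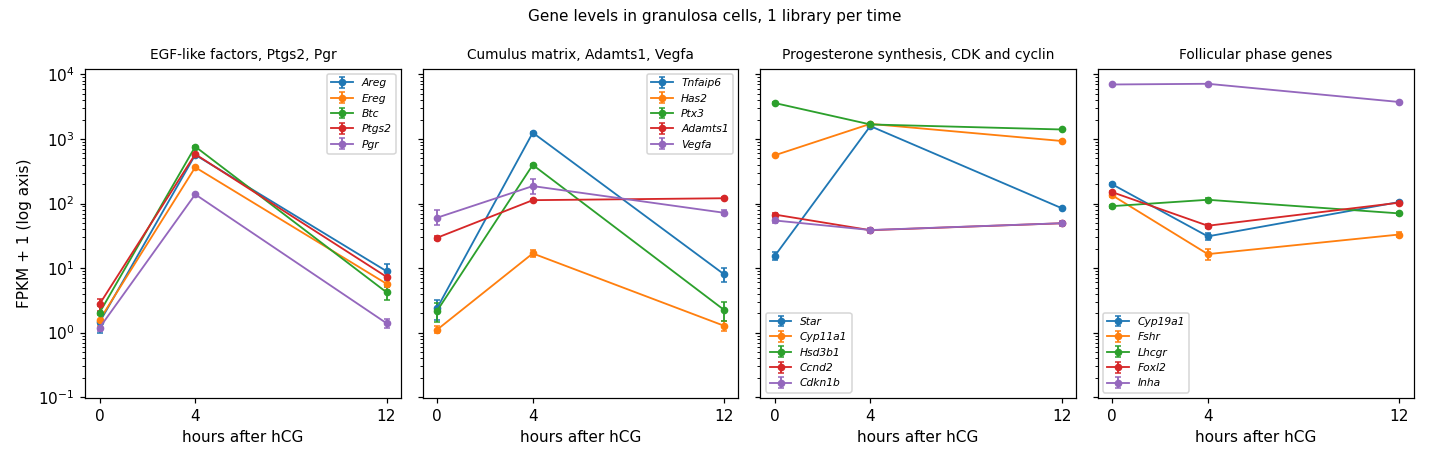
Levels of 20 genes fixed before the data were examined, in granulosa cells at 0, 4 and 12 h after hCG (x axis), as FPKM + 1 on a log axis; each point is 1 library and each bar the deposited interval. Areg, Ereg, Btc, Ptgs2, Pgr, Tnfaip6, Has2 and Ptx3 peak at 4 h, Adamts1 is at 112 FPKM at 4 h and 120 at 12 h, and Cyp19a1, Fshr and Foxl2 have their lowest level at 4 h.

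All 22 immediate early genes had a positive log2 fold from 0 to 4 h, and 16 were higher by the 2-fold rule (median 2.26). Egr3 went from 0.722 to 85.3 FPKM, Ier3 from 20.3 to 297, Junb from 8.10 to 95.5 and Ier5 from 3.54 to 37.2. Of 19 genes that damp MAPK and cAMP signalling, 14 were higher and none lower (median 2.14), among them the EGF receptor inhibitor Errfi1 (12.5 and 282 FPKM), the cAMP-responsive modulator Crem (6.74 and 106), the phosphodiesterase Pde4b (0.801 and 21.3) and Spry2 (11.2 and 112). Pde7b, a second phosphodiesterase gene, was at 12.9 and 9.95 FPKM. Both list medians exceeded those of all random lists.

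Genes of progesterone synthesis moved apart. Of 15 measured, 5 were higher at 4 h, 1 was lower and 9 were neither (median 0.51, above 97.8% of random lists); with libraries rescaled to a common sum 5 were higher and 3 lower (median 0.26). The cholesterol carrier Star was at 14.3 FPKM (12.2 to 16.5) before hCG and 1583 at 4 h, the electron carrier Fdx1 at 182 and 1890, the lipoprotein receptor Scarb1 at 268 and 1648, and the reductase Por at 37.9 and 203. Cyp11a1, the side-chain cleavage enzyme, was at 557 and 1713 FPKM (log2 fold 1.62). Hsd3b1, which makes progesterone from pregnenolone and belongs to a family of near-identical genes, was lower, at 3609 and 1679 FPKM. In cholesterol synthesis 8 of 22 genes (4 on libraries rescaled to a common sum) were higher and 1 lower (median 0.51, above 99.8% of random lists), with Cyp51 at 35.4 and 195 FPKM, Sc5d at 56.7 and 241, and Mvk at 25.1 and 11.7.

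Follicular phase genes were the list with the lowest median, -0.71, below all random lists. Of its 22 genes, 7 were lower at 4 h, 2 were higher and 13 were neither; with libraries rescaled to a common sum 12 were lower and 1 higher (median -1.02). Beside Inhbb, the natriuretic peptide Nppc was at 159 FPKM at 0 h (log2 fold -3.32), the FSH receptor Fshr at 133 and 15.5, Hsd17b1 at 1065 and 151 and the aromatase Cyp19a1 at 198 FPKM at 0 h (log2 fold -2.68). The transcription factor Foxl2 was at 149 (142 to 156) and 44.3 FPKM (40.7 to 47.9). Igf1r was higher, at 25.4 and 74.2 FPKM. The LH receptor Lhcgr, at 90.1 and 113 FPKM, and the inhibin alpha subunit Inha, at 6986 and 7163, stayed within 2-fold.

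In the mitosis list 23 of 24 genes had a negative log2 fold (median -0.53, above 0.02% of random lists), but only Ccnb2, at 86.3 and 26.0 FPKM, was lower by the 2-fold rule on the deposited scale, against 6 genes with libraries rescaled to a common sum (median -0.84). Cdk1 was at 51.7 and 55.3 FPKM. None of the 24 genes of DNA replication passed the rule (median -0.21), and 2 were lower on the rescaled libraries; Rfc4 was at 33.6 and 16.6 FPKM and Pcna at 51.6 and 81.2. Of 7 CDK inhibitors Cdkn1a was higher (6.85 and 58.6 FPKM) and Cdkn2a (8.04 and 1.74) and Cdkn2c (27.6 FPKM at 0 h, log2 fold -1.03) were lower. Cdkn1b, at 53.7 and 37.9 FPKM, and the cyclin Ccnd2, at 66.5 and 37.7, were within 2-fold.

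Lists of vessel growth, inflammation and matrix turnover held more higher than lower genes at 4 h on both scales. Of 16 measured angiogenic factors 7 were higher and 1 lower (median 0.76, above 99.99% of random lists): Efnb2 was at 1.75 and 36.3 FPKM, Vegfc at 12.3 FPKM at 4 h (log2 fold 2.25), Vegfa at 59.3 and 185, and Vegfb was lower, at 46.8 and 20.1. Of 12 measured cytokines and chemokines 7 were higher and none lower on the deposited scale (median 1.29; on libraries rescaled to a common sum 7 and 1), led by the chemokine receptor Cxcr4 (2.37 and 314 FPKM) and the interleukin receptor Il1r1 (12.3 and 74.7), while Il6 was listed at 0 before hCG and was at 4.07 FPKM. Of 17 matrix proteases and inhibitors 10 were higher and none lower on the deposited scale (median 1.76; on libraries rescaled to a common sum 9 and 2), with the inhibitor Timp1 at 34.6 and 521 FPKM, the plasminogen activator Plau at 78.7 and 1105, Pappa at 0.941 and 23.4 and Adamts1 at 28.5 and 112. In the prostaglandin list 6 of 16 genes were higher and 2 lower (median 0.81): next to Ptgs2 stood the transporter Slco2a1 (3.09 and 30.7 FPKM) and the receptor Ptger4 (0.539 and 7.47), and the synthase Ptges was lower (68.4 and 27.0). The last 3 medians exceeded those of all random lists.

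Among 19 measured genes of glycolysis and glucose uptake 4 were higher and 4 lower (median -0.36, above 1.22% of random lists; on libraries rescaled to a common sum 3 and 5, median -0.66). Gapdh, counted here at 0.909 and 1.02 FPKM, is among the ubiquitous genes listed near 0 that the closing part describes. The glucose transporter Slc2a1 was at 25.1 and 149 FPKM and Hk2 at 9.16 and 31.6. Pfkm was at 27.8 and 8.10 and the lactate transporter Slc16a3 at 46.4 and 16.7. None of the 8 pentose phosphate genes was past 2-fold (median -0.18), against 2 lower on libraries rescaled to a common sum (median -0.49); H6pd, at 15.8 and 32.4 FPKM, was just under the threshold. Of 24 genes of TGF-beta superfamily signalling 8 were higher and 3 lower (median 0.46; on libraries rescaled to a common sum 6 and 3, median 0.23), with Tgfb1 at 10.4 and 42.1 FPKM, Id2 at 36.3 and 116, Grem1 at 78.0 and 21.7 and the BMP receptor Bmpr1b at 92.4 and 33.8. In the hypoxia list 5 of 16 genes were higher and 2 lower (median 0.40; on libraries rescaled to a common sum 4 and 3, median 0.15), Egln3 being at 0.791 and 34.0 FPKM and Bnip3 at 55.6 and 9.95. Of 27 measured enzymes of histone methylation and acetylation only the demethylase Kdm6b was higher (14.4 and 31.5 FPKM), none was lower, and the list median was 0.28 on the deposited scale; with libraries rescaled to a common sum none was higher, 1 was lower and the median was -0.02.

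Markers of other cell types differed between the 0 h and 4 h libraries as well. Surface epithelium markers had a median log2 fold of 1.03, with 4 of 8 higher, or 2 on libraries rescaled to a common sum (Krt18 7.70 and 36.5 FPKM, Krt7 4.28 and 14.7) and Aldh1a1 lower (412 and 128). Endothelial markers had a median of 0.65, with Kdr at 1.54 and 7.92 FPKM, and leukocyte markers of 0.59, with Cd68 at 5.39 and 22.7. All 3 measured neutrophil markers were higher: S100a8 went from 1.59 to 10.2 FPKM, and S100a9 and Camp were listed at 0 before hCG and were at 10.8 and 2.32 FPKM. Smooth muscle markers had a median of 0.49 (Tagln 45.0 and 101 FPKM), and none was higher on libraries rescaled to a common sum (median 0.31). Theca and stroma markers had a median of 0.22 that became -0.09 with libraries rescaled to a common sum, and only Mgp (70.9 and 371 FPKM) was higher. All 11 measured oocyte markers had negative log2 folds within 2-fold (median -0.38), and erythroid markers had a median of -0.70; on libraries rescaled to a common sum 2 oocyte and 3 erythroid markers were lower, with an oocyte median of -0.68. The near-identical globin genes Hbb-b1 and Hbb-bs were at 1199 and 647 and at 57.2 and 149 FPKM. Heat shock and stress genes had a median of 0.52, with 5 of 14 higher, among them Gadd45a (26.0 and 87.4 FPKM), and Hspa1b lower (5.78 and 0.893); on libraries rescaled to a common sum 4 were higher and 2 lower (median 0.22). Housekeeping genes had a median of 0.10 that became -0.15 with libraries rescaled to a common sum. Ywhaz was higher (81.1 and 231 FPKM). This list holds Gapdh, Ppia and Rpl19, which were near 0 in each library as the closing part describes. No gene of the mitochondrially encoded list was among the transcripts analysed.

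**Figure D2:**
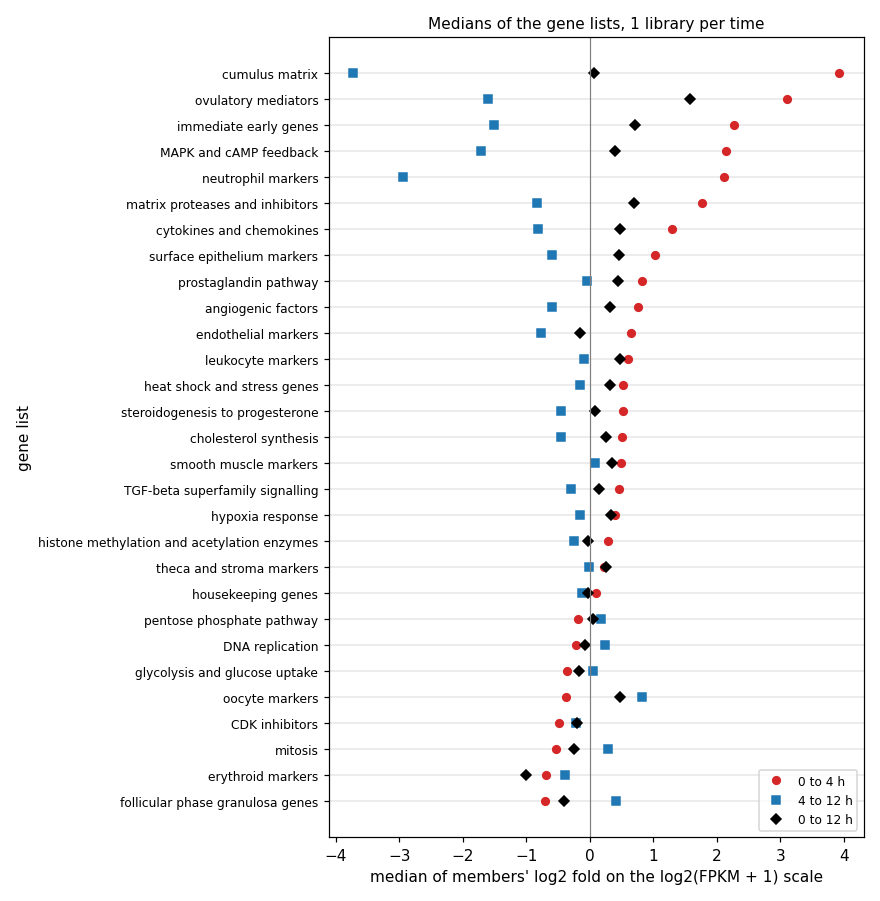
Median log2 fold of the members of 29 gene lists (y axis) on the log2(FPKM + 1) scale (x axis) for 0 to 4 h (circles), 4 to 12 h (squares) and 0 to 12 h (diamonds), each between 2 libraries. The cumulus matrix list has medians of 3.92 and -3.72 for the first and second interval and 0.07 from 0 to 12 h; several medians, among them those of histone enzymes, theca and housekeeping genes, change sign with libraries rescaled to a common sum.

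The comparison of 12 h with 4 h asked what followed between the early response and the time near ovulation. Many of the genes with the largest folds up at 4 h had the largest folds down at 12 h: Sult1e1 was at 2316 and 0.486 FPKM (log2 fold -10.61), Nts at 2009 and 2.64 (-9.11), Btc at 762 and 3.21 (-7.50), Ptx3 at 396 at 4 h (-7.46), Tnfaip6 at 1251 and 7.01 (-7.29), Pgr at 138 and 0.399 (-6.63) and Ptgs2 at 581 and 6.32 (-6.31). The EGF-like factor Epgn was at 102 and 0.171 FPKM, and Npy was listed at 0 at 12 h. Inhbb was higher at 12 h, at 542 FPKM (532 to 552) against 27.0 at 4 h, ahead of Jakmip3 (1.39 and 14.9 FPKM), Ldhd (2.41 and 16.0), Capn5 (1.81 and 12.9), Mybpc3 (2.15 and 13.1) and Kctd14 (18.3 and 82.1).

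By the 2-fold rule 639 of 13242 genes were higher at 12 h than at 4 h and 1043 were lower, 40 and 150 of them by at least 8-fold. Genes higher at 12 h made up 38.0% of those past the threshold. They made up 72.2% with each library rescaled to a common sum, where 2219 genes were higher and 855 lower and the median of all genes moved by 0.37, and 70.6% with libraries brought to the mean of their sums. With median-of-ratios scaling, which lay close to the deposited scale, they made up 41.4%, with 708 genes higher and 1001 lower.

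Of the ovulatory mediators 13 of 20 were lower at 12 h than at 4 h and 1, the endothelin Edn2 (7.83 and 29.6 FPKM), was higher (median -1.60). Areg was at 567 and 7.96 FPKM and Ereg at 363 and 4.72. Of 7 cumulus matrix genes 5 were lower (median -3.72), Vcan being at 1806 and 119 FPKM. Immediate early genes were lower in 14 of 22 cases (median -1.51), with Egr3 at 85.3 FPKM at 4 h (log2 fold -4.75) and Fosl1 at 6.51 and 0.508, and Myc was at 47.8 and 57.6. Feedback genes of MAPK and cAMP signalling were lower in 12 of 19 cases (median -1.71), with Crem at 106 and 12.3 FPKM and Errfi1 at 282 and 35.4. Each of these 4 medians lay below those of all random lists. Star was at 1583 and 83.8 FPKM, Scarb1 at 1648 and 283, Por at 203 and 44.0 and Fdx1 at 1890 and 485, and 4 of the 15 genes of progesterone synthesis were lower and none higher (median -0.45, or -0.10 on libraries rescaled to a common sum). Cholesterol synthesis genes had a median of -0.46, with 6 of 22 lower (Sc5d 241 and 68.1 FPKM) and Mvk higher (11.7 and 30.8); on libraries rescaled to a common sum 4 were lower and 3 higher (median -0.19).

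Follicular phase genes were higher at 12 h than at 4 h in 6 of 22 cases and lower in 1 (median 0.40, above 99.99% of random lists; 0.80 on libraries rescaled to a common sum). Beside Inhbb, Cyp19a1 was at 105 FPKM at 12 h (log2 fold 1.77), Hsd17b1 at 151 and 445, Foxl2 at 44.3 and 102 and Fshr at 15.5 and 32.1 (log2 fold 1.01), while the inhibin beta A subunit Inhba was lower, at 784 and 208. The mitosis list had a median of 0.29, with Ccnb2 higher at 26.0 and 57.6 FPKM and the other 23 genes within 2-fold. Medians of DNA replication (0.24) and pentose phosphate genes (0.17) came with no gene past 2-fold. On libraries rescaled to a common sum these 3 medians were 0.67, 0.63 and 0.56, with 3, 1 and 1 genes higher. Matrix proteases and inhibitors were lower in 7 of 17 cases (median -0.84), with Plau at 1105 and 200 FPKM and Pappa at 23.4 and 3.95, whereas Adamts1 stayed at 112 and 120. Angiogenic factors were lower in 4 of 15 cases (median -0.60; Vegfa 185 and 70.9 FPKM), and cytokines and chemokines in 5 of 12 (median -0.82; Cxcr4 314 and 21.7). On libraries rescaled to a common sum the medians of these 3 lists were -0.45, -0.21 and -0.66, and 1 angiogenic factor was higher and 3 lower. Kdm6b was the only histone enzyme past 2-fold (31.5 and 13.4 FPKM, lower), and the list median was -0.26 on the deposited scale; with libraries rescaled to a common sum no gene was past 2-fold and the median was 0.10.

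All 11 measured oocyte markers had positive log2 folds between 4 h and 12 h, 3 of them past 2-fold (median 0.82) and 10 with libraries rescaled to a common sum (median 1.22), with Mos at 3.02 and 8.92 FPKM, Oosp1 at 22.1 and 48.8 and Npm2 at 12.8 and 28.5. Endothelial markers were lower in 4 of 9 cases (median -0.77; Kdr 7.92 and 1.24 FPKM, Tie1 3.82 and 0.865), and surface epithelium markers had a median of -0.60 with only Krt7 past 2-fold (14.7 and 6.78 FPKM). On libraries rescaled to a common sum their medians were -0.45 and -0.24, with 3 endothelial and no epithelial markers lower. The neutrophil genes S100a9 (10.8 and 0.266 FPKM) and S100a8 (10.2 and 0.463) were lower. Erythroid markers had a median of -0.39, or -0.03 on libraries rescaled to a common sum, with Hbb-bs lower (149 and 11.3 FPKM). Median log2 folds of leukocyte (-0.09), theca and stroma (-0.02), heat shock (-0.16) and housekeeping genes (-0.13) were negative on the deposited scale and positive with libraries rescaled to a common sum. That of smooth muscle markers was 0.09, or 0.45 on the rescaled libraries.

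The comparison of 12 h with 0 h asked which differences were present at 12 h relative to the cells before hCG. The largest folds up were those of the aldo-keto reductase Akr1b7, at 0.216 and 153 FPKM (143 to 163; log2 fold 6.98), Ly6d (1.09 and 35.8), the secreted glycoprotein osteopontin, Spp1 (21.0 and 358), and Edn2 (1.08 and 29.6). The steroid hydroxylase Cyp11b1 and Sprr2g were listed at 0 before hCG and were at 7.05 and 6.52 FPKM. The largest folds down were those of the cartilage matrix protein Comp, at 125 and 1.70 FPKM (log2 fold -5.54), the protease inhibitor Serpina5 (13.4 and 0.0888), the BMP antagonist Grem1 (78.0 and 5.13), Zpld1 (24.7 and 1.15) and the WNT antagonist Frzb (20.7 and 2.35). Akr1b7 lies on chromosome 6 at 34412362 to 34423137 and Comp on chromosome 8 at 70373548 to 70382066. The short RNA AF357399 was at 171 FPKM before hCG and listed at 0 at both later times.

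Of 13026 genes 411 were higher at 12 h than at 0 h and 332 were lower, 52 and 43 of them by at least 8-fold; with libraries rescaled to a common sum 768 were higher and 431 lower, and with libraries brought to the mean of their sums 507 and 301. Ovulatory mediators were higher in 13 of 18 cases and lower in 1 (median 1.58, above all random lists): beside Edn2 stood the sphingosine kinase Sphk1 (0.540 and 9.54 FPKM), Areg (0.450 and 7.96) and Cited4 (5.06 and 35.3), and Fosl2 was lower (131 and 62.8). Matrix proteases and inhibitors were higher in 7 of 17 cases (median 0.70), with Timp1 at 34.6 and 191 FPKM, Mmp19 at 1.32 and 10.5, Adamts1 at 28.5 and 120 and Adamts4 at 0.992 and 5.65. In the cumulus matrix list Tnfaip6 (1.40 and 7.01 FPKM) and Itih2 (12.7 and 27.5) were higher, Has2 was at 0.111 and 0.277, and the median was 0.07. Immediate early genes were higher in 5 of 20 cases, or 9 on libraries rescaled to a common sum, and lower in 1 (median 0.70), with Ier3 at 20.3 and 102 FPKM, Nr4a1 at 11.9 and 39.4 and Fosl1 lower at 3.09 and 0.508.

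Follicular phase genes were lower at 12 h than at 0 h in 6 of 22 cases and higher in 1 (median -0.41, below all random lists). Nppc was at 159 and 32.5 FPKM, Fshr at 133 and 32.1, Inhba at 699 and 208 and the activin-binding Fst at 597 and 216, and Wt1 was higher at 13.2 and 31.5. Cyp19a1, at 198 and 105 FPKM, Foxl2, at 149 and 102, and Inha, at 6986 and 3742, were within 2-fold. Star (14.3 and 83.8 FPKM) and Fdx1 (182 and 485) were higher and Hsd3b1 lower (3609 and 1402) in a list with a median of 0.08, and no cholesterol synthesis gene was past 2-fold (median 0.26). All but 1 of the 24 mitosis genes had a negative log2 fold and none passed 2-fold (median -0.26). Among CDK inhibitors Cdkn2a (8.04 and 0.529 FPKM) and Cdkn2b (2.14 and 0.216) were lower and Cdkn1a (6.85 and 15.8) was higher. In TGF-beta signalling Id2 (36.3 and 120 FPKM) and Smad6 (2.90 and 10.2) were higher and Grem1 and Id1 (88.6 and 35.4) lower. Prostaglandin genes were higher in 4 of 16 cases (median 0.44), Ptgs1 being at 1.40 and 8.03 FPKM and Akr1c18 at 5.41 and 19.2. Medians of oocyte (0.47), leukocyte (0.47), surface epithelium (0.46), smooth muscle (0.35) and theca and stroma markers (0.25) were positive and those of erythroid (-1.01) and endothelial markers (-0.15) negative, with Cd52 at 4.01 and 17.5 FPKM, Aldh1a1 at 412 and 101 and Mgp at 70.9 and 191.

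Taking the 3 libraries in order sorted genes into 6 time courses, which are not independent because the comparisons share libraries, and which overlap in 20 genes that are both transiently higher and lower at 12 h only and in 4 that are both transiently lower and higher at 12 h only. The largest class on the deposited scale held 865 genes that were higher at 4 h than at both other times by the 2-fold rule between neighbouring times, 63.8% of those higher at 4 h, and Sult1e1, Nts, Areg, Btc, Ereg, Ptgs2, Pgr, Tnfaip6, Ptx3 and Star were among them. A further 151 genes, including Akr1b7, Ly6d, Spp1, Bves (3.31, 44.1 and 30.9 FPKM at 0, 4 and 12 h) and Asgr1 (0.636, 12.7 and 11.8), were higher at 4 h and kept at 12 h. In 81 genes the level was higher at 12 h only, as in Ldhd (3.20, 2.41 and 16.0 FPKM). Transiently lower at 4 h were 358 genes, among them Inhbb, Mro, Nppc, Fshr, Kcne2 and Fam162b. Neither transient class requires a return to the 0 h level. By the 2-fold rule Inhbb, Nppc and Fshr were still lower at 12 h than at 0 h, and Areg and Star still higher. Tmprss13 (9.90, 0.275 and 1.13 FPKM) and Tulp2 (11.4 FPKM at 0 h and 1.10 at 12 h) belonged to the 165 genes that were lower at 4 h and kept at 12 h. The 74 genes lower at 12 h only included Comp (125, 101 and 1.70 FPKM), Serpina5, Inhba and Zpld1, which at 24.7, 119 and 1.15 FPKM is also in the transiently higher class. On libraries rescaled to a common sum the transiently higher class held 686 genes, the transiently lower class, then the largest, 1278 and the class higher at 12 h only held 248. Median-of-ratios scaling, which lay close to the deposited scale, gave 828 transiently higher genes against 392 transiently lower.

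Isoform shares were compared in genes with several annotated transcripts and at least 10 FPKM in both libraries. A change of at least 50 percentage points in 1 isoform's share was found in 141 of 2008 genes from 0 to 4 h, in 131 of 2048 from 4 to 12 h and in 111 of 2161 from 0 to 12 h. The most extreme were near-complete changes of the estimated share, whose source is left open in the closing part. In Anapc15, a subunit of the anaphase-promoting complex, 1 isoform held nearly all of 16.3 FPKM at 0 h and 0.00547% of 12.9 FPKM at 4 h. In Enoph1 1 isoform went from nearly all of the gene's FPKM at 0 h to 0% at 4 h, and in the membrane glycoprotein gene Pdpn the share went from nearly all at 0 h to 0.0503% at 4 h and back to nearly all at 12 h. Atxn7l3 (0.0160% at 12 h, from nearly all) and Mrto4 (0.484% at 4 h, to nearly all) led from 4 to 12 h together with Pdpn. From 0 to 12 h Anapc15, Mrto4 and Nme7 (0% and 98.9%) led. The deposited intervals of the isoform with the largest change lay apart in 100, 89 and 81 of these genes.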

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

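The length trend correction, the rescaling of libraries to the mean of their sums and the requirement that the switching isoform's intervals lie apart were chosen after seeing the data. Of 450 folds of named genes none that passed 2-fold changed sign under 8 settings. The pseudocounts, the scalings used and leaving out short RNAs could not have turned such a sign. Only the main isoform setting and the length trend correction could have done so. Of 258 folds past 2-fold, 49 dropped under it with a pseudocount of 5 FPKM. With libraries rescaled to a common sum 11 did so, and 13 with libraries brought to the mean of their sums. Removing the length trend took 10 under it, median-of-ratios scaling 2 and the main isoform only 1. Of 86 medians of the fixed lists, 17 moved by at least their standard error with a pseudocount of 5 FPKM, 8 with 0.1 FPKM and 5 with the main isoform only. With libraries rescaled to a common sum 29 moved, besides the 3 histone enzyme and TGF-beta medians given below. Those 3 lay outside the central 95% of random lists and changed sign. Medians inside that range also changed sign but were not counted as reversed. Among them, from 4 to 12 h, the prostaglandin median of -0.05 became 0.30 and the hypoxia median of -0.16 became 0.21. Dropping the filter on low values changed no count, because a 2-fold difference with a pseudocount of 1 FPKM already requires more than 1 FPKM. Median-of-ratios scaling, which lay close to the deposited scale, and removal of the length trend kept each gene count within 1.5 times. So did intervals that lie apart for the counts of the 3 comparisons, the time courses not being run under that setting. Counts on whole fragments were not run as a test, since 1 library per time leaves no replicates and multi-isoform genes hold fractions of fragments. No paired analysis was possible because each time has 1 library.

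Rescaling to a common sum of 1000000 gave 2185 genes lower from 0 to 4 h, 2219 higher from 4 to 12 h, 768 higher from 0 to 12 h, 236 higher at 4 h and kept, 248 higher at 12 h only and 1278 transiently lower. This setting changes the relative scale of the libraries and also raises all values against the pseudocount and the floor. Bringing libraries to the mean of their sums, which changes the relative scale only, gave 1724 lower from 0 to 4 h, 1668 higher and 693 lower from 4 to 12 h, 132 higher at 12 h only and 964 transiently lower, and histone enzyme medians of -0.016 and 0.099 and a TGF-beta median of 0.0066 for the comparisons named next. The sum of 1000000 turned the histone enzyme medians to -0.0164 (0 to 4 h) and 0.10 (4 to 12 h) and the TGF-beta median to 0.0018 (4 to 12 h). With a pseudocount of 0.1 FPKM, which lets low genes pass, 1422 genes were lower from 0 to 4 h, 1130 higher from 4 to 12 h, 729 higher and 523 lower from 0 to 12 h, 283 higher at 4 h and kept, 186 higher at 12 h only, 658 transiently lower, 262 lower at 4 h and kept and 128 lower at 12 h only. With 5 FPKM, which damps them, 781 were higher and 345 lower from 0 to 4 h, 155 higher and 618 lower from 4 to 12 h, 166 higher and 144 lower from 0 to 12 h, 536 transiently higher, 65 higher and kept, 37 higher at 12 h only, 81 transiently lower, 74 lower and kept and 34 lower at 12 h only. In the same order of results a 1.5-fold threshold gave 2525, 2481, 2141, 2120, 1145, 873, 1675, 409, 312, 1399, 407 and 175 genes, and a 4-fold threshold 472, 121, 59, 338, 96, 76, 287, 40, 29, 17, 42 and 22. The main isoform alone gave 523 genes lower from 0 to 12 h, 258 higher at 4 h and kept and 168 lower at 12 h only; the cause was not tested. A filter of 5 FPKM left 49 genes lower at 12 h only, and leaving out short RNAs 50 higher at 12 h only, both by testing fewer genes. Isoform switches numbered 233, 218 and 191 (0 to 4, 4 to 12 and 0 to 12 h) at a floor of 5 FPKM, 34, 27 and 29 at 30 FPKM, and 377, 382 and 337 at a share change of 30 points.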

Other observations

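The families in the first 2 paragraphs, the tests on coverage, on sequence shared with pseudogenes and on other cell types, and the one on counting noise in transiently lower genes were chosen after their results were seen; the length trend correction was added after seeing the data, its bound before its result. Genes of neuropeptides and regulated secretion were gathered because Nts, Nmu and Npy had such large folds, and the list contains them, so it describes that observation and does not test it. Of 21 listed genes 13 reached 1 FPKM at 0 or 4 h, and 9 of these were higher at 4 h and none lower. Beside Nts, Npy and Nmu, the peptide gene Adcyap1 was at 0.0402 FPKM at 0 h and 92.7 at 4 h (log2 fold 6.49, then -5.97) and Tac1 at 6.49, 108 and 4.98, the vesicle fusion protein Snap25 was listed at 0, then at 146 and 1.56 FPKM, and the granin Chgb was at 0.267, 10.5 and 1.12 FPKM. Vip and Cartpt were listed at 0 in all 3 libraries. Of 21 actin and adhesion genes 8 were higher at 4 h, 13 neither and none lower (median 0.85), and 8 were lower at 12 h than at 4 h (median -0.72). With libraries rescaled to a common sum 6 were higher at 4 h and 3 lower at 12 h (medians 0.60 and -0.33). Vcl was at 42.5, 175 and 41.9 FPKM, Tpm4 at 106, 568 and 160, Ezr at 41.6, 172 and 68.0 and the integrin Itga5 at 14.5, 74.3 and 26.8.

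Genes of mitochondrial respiration had small folds: from 0 to 4 h 2 of 36 complex I, none of 16 tricarboxylic acid cycle and 2 of 35 mitochondrial ribosome genes were lower by the 2-fold rule, and from 4 to 12 h none passed it. With libraries rescaled to a common sum 8 complex I genes were lower at 4 h and 6 higher at 12 h than at 4 h. Of 36 subunits of complex I, 33 had a negative log2 fold from 0 to 4 h (median -0.45, below all random lists). From 4 to 12 h 32 had a positive one (median 0.26). Rescaling to a common sum gave complex I medians of -0.75 and 0.65. It moved the median of all genes the same way, by -0.29 and 0.37, so it could not have reversed either direction. Ndufv3 was at 156, 69.0 and 119 FPKM and Ndufc1 at 282, 122 and 176. Mitochondrial ribosome genes had medians of -0.25 and 0.26, with Mrpl13 at 104, 49.5 and 89.7 FPKM, and tricarboxylic acid cycle enzymes of -0.22 and 0.19, with Mdh2 against the trend at 286, 346 and 271. On libraries rescaled to a common sum these medians were -0.56 and 0.65 and -0.53 and 0.58. Proteasome (median 0.10), chaperonin CCT (0.11) and unfolded protein response genes (0.27; Atf4 150, 357 and 160 FPKM) had positive medians from 0 to 4 h that became negative with libraries rescaled to a common sum. Interferon response genes had a median of -0.50 from 0 to 4 h with none of 11 past 2-fold, and of -0.84 with 2 lower on libraries rescaled to a common sum.

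The 4 h library stood apart from both others, with 865 transiently higher and 358 transiently lower genes. After a trend with transcript length was removed the 2 classes held 97.1% as many genes, and 89.8% of the original genes were still in their class, which argues against that trend as the whole cause. A deposited 4 h interval lay above both others in 90.2% of the transiently higher genes, which argues against counting noise there, and below both others in 75.7% of the transiently lower genes. Simulated counting noise called 19 of 12425 unchanged genes from 0 to 4 h, both directions together, against 931 genes lower in the data. This argues against Poisson noise in gene counts as the source of most of these 931 calls. The transiently lower class was not counted in the simulation, and errors in dividing fragments between isoforms were not simulated. Whether counting noise made part of that class stays open, above all for members whose intervals overlap. A lower share of granulosa cells would raise other cell types alike if these were recovered alike, and 5 of 7 such lists had medians above 0. Those of surface epithelium and oocyte markers lay 1.41 apart with opposite signs (standard error 0.513). That pair was compared after its medians were seen, so the difference cannot decide, and a lower share of granulosa cells stays open. The time after hCG is the explanation the design names, and it stays open beside any property of the single 4 h library, beside a lower share of granulosa cells and beside a gain of 1 other cell type.

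Isoform switches were rarer at high coverage. Of genes with at least 100 FPKM in both libraries 1 of 142 had a switch from 0 to 4 h (0.704%), against 107 of 1256 at 10 to 30 FPKM (8.52%), so that the share at high coverage was 8.27% of that at low coverage, which is consistent with low coverage as a source of some switches. The simulation gave 0 false switches but drew each isoform on its own, so it cannot show whether dividing shared fragments at low coverage gives switches. The isoform intervals lay apart in 100 of 141 switches, Anapc15 and Pdpn among them, so other sources stay open for these. Sequence shared between isoforms cannot be told apart from other sources: the 2 main isoforms of switching genes were separated by 62.4% as many 31-mers as in other genes, but both sequences were found for only 72.3% of switching genes. Regulated splicing or promoter choice was not tested.

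Some genes that most cells express strongly were listed near 0 in each library: Gapdh was at 0.909, 1.02 and 0.894 FPKM, Ppia at 1.13, 0.155 and 1.30, Eno1 at 0, 0 and 0.677 and Rpl19 at 2.91, 4.32 and 5.30, and 32 of 82 ribosomal protein genes averaged under 10 FPKM. The 32 include the paralogs Rpl3l, Rpl10l and Rpl39l (means of 0, 0.142 and 1.27 FPKM), which may be truly low in these cells. A candidate explanation is sequence shared with pseudogenes, to which fragments could have been lost. The median level of 45 ribosomal protein genes that shared at least 50% of their 31-mers with pseudogene transcripts was 6.03% of that of 8 genes that shared under 10%, 21.0 against 348 FPKM, but 29 genes between these bounds were at 32.4 FPKM and Rps15, with 58.9% shared, averaged 1011. A first measure, the number of near-identical copies, put only 2 genes in its upper class and was replaced after it was seen. The class of 8, which includes Rpl3l and Rpl39l, is too small to decide, so this explanation and the submitters' handling of such fragments stay open.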
